A study of Rattus norvegicus with 9 samples.

How the data were processed

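Expression was measured on 9 arrays of rat hippocampal RNA, 3 each for control in artificial cerebrospinal fluid, 1 h of ketone bodies and 6 h of ketone bodies; groups and replicate numbers come from the labels. The deposited table holds 31099 probe sets as linear signal intensity, 1 column per array. The software, chip description and any filter are not given in the sources used here; that the scale is linear was read from the values. The deposited intensities are positive, with 0 values at or below 0, and their mean without the lowest and highest 2% of probe sets is 150.05 on every array, which is what global scaling of each array to a common trimmed mean gives. No counts lie behind the values, so the number of arrays sets the precision, and no background was measured.

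All choices in this paragraph were fixed before the data were examined. Values were taken as log2(signal + 16). The array medians on that scale spanned 0.206, over the limit of 0.2 set for using them as deposited, so quantile normalization followed. The 57 control probe sets were left out, and so were probe sets whose mean over all arrays lay under the 40th percentile (log2 5.21, a signal of about 21.0), which left 18625. Each comparison (1 h against control, 6 h against control, 6 h against 1 h) came from 1 fit with limma 3.58.1 in R 4.3.3, with 1 coefficient per group, 6 residual degrees of freedom, moderated variances with an intensity trend and Benjamini-Hochberg adjusted p-values at a threshold of 0.05. The moderated F test asked for any difference among the 3 groups.

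Gene names came from the platform annotation, checked through Entrez numbers against a rat gene table: 20764 matched, 68 did not and 0 symbols changed. Of 31042 probe sets, 20826 are listed with 1 gene, 436 with several and 9780 with none; of those tested, 14450, 315 and 3860. Probe sets with several genes or none are reported without a gene name, with exceptions stated beside the oxidative phosphorylation list and the 6 h calls.

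There were 24 gene lists and 15 lists of cell type markers, tested by limma's camera with a preset inter-gene correlation of 0.01 on the probe set with the highest mean per gene (10707 genes), 2-sided, adjusted over the 36 lists with at least 4 genes measured. Camera with an estimated correlation and fry were the alternatives. Members that rose or fell were counted over all probe sets and adjusted over the list alone. The named genes are, per comparison, those passing with a single gene name and no overlap between groups, or where fewer than 5 pass in a direction, the 5 with the smallest p; from each list up to 4 members that pass over the list alone, or 2 with the smallest p and their values; and Bdh1, Oxct1, Slc16a1, Slc16a7, Pdk4, Fos and Bdnf. One further item of that rule is not reported here. Probe sets without a single gene name that passed are described because they are so few, which was decided after their values were seen.

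RNA quality was read per array from the log2 ratio of the 3' to the 5' control probe sets of beta-actin and Gapdh, compared by exact 2-sided permutation tests. The overlap of the 1 h and 6 h changes was set beside 100 simulations of unchanged groups that share the controls. Alternatives were the values as deposited, centring on array medians, a pseudocount of 1 or 64, no filter or the 60th percentile, no intensity trend, array weights, a block on replicate numbers, only the compared groups, 1 probe set per gene, and leaving out each array. A covariate for the 3'/5' ratio, leaving out 2 arrays and a narrower ribosomal list were added after seeing the data.

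The steps were tested on simulated data with the same 18625 probe sets and 200 changed ones in each of 10 runs of a simulated 1 h comparison. They called 13.9% of probe sets changed by 0.5 on the log2 scale, 79.3% of those changed by 1 and 98.2% of those changed by 2, with 0 wrong signs. False calls were 5.49% of all calls, and 1 call arose in an unchanged comparison over all runs. A list shifted by 0.3 was called and 0 other lists were. The simulated noise was drawn independently for each probe set and array. These rates therefore do not cover correlation between genes or structure shared across arrays, and do not test the preset correlation on the real data. Figures were drawn with matplotlib.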

Results

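Gene expression was measured with Affymetrix-type rat arrays on RNA that the labels describe as from neurons of the hippocampus. There were 3 groups with 3 arrays each: control in artificial cerebrospinal fluid only, 1 h of ketone bodies and 6 h of ketone bodies. The labels give no exposure time for the control. They also do not say that the replicates are separate animals or cultures, so each p below measures only the spread between these 9 arrays. The median of log2(signal + 16) per array ran from 5.67 to 5.88 before normalization. The number of arrays limits the precision. Arrays of the same group correlated at 0.949 to 0.987 over the tested probe sets, and arrays of different groups at 0.945 to 0.988, so the groups did not stand apart as a whole. The first principal component held 45.0% of the variance.

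The question of the first comparison was which transcripts differed after 1 h of ketone bodies. Ccl2, which encodes a chemokine that attracts monocytes, rose with a log2 change of 1.34 ± 0.13 (SE, n = 3 arrays per group throughout; adjusted p = 0.0155). Cxcl10, an interferon-inducible chemokine, rose by 1.03 ± 0.12 (adjusted p = 0.0205). Csrnp1, a nuclear protein gene induced early by signalling, rose by 0.94 ± 0.10 (adjusted p = 0.0205). The chemokine Cxcl1 (1.09 ± 0.15, adjusted p = 0.051) and the aspartate aminotransferase Got1 (1.13 ± 0.16, adjusted p = 0.051) did not pass. Among negative log2 changes with a gene name none passed. The smallest p values there belonged to the kinase subunit Camk2a of excitatory synapses (-0.89 ± 0.13, adjusted p = 0.051), the noncoding RNAs Meg3 (-0.79 ± 0.12, adjusted p = 0.0839) and Snhg11 (-0.79 ± 0.12, adjusted p = 0.0861), the histone methyltransferase Setd1b (-0.73 ± 0.14, adjusted p = 0.215) and the postsynaptic scaffold Dlg4 (-0.83 ± 0.16, adjusted p = 0.236). The other Camk2a probe sets gave -0.59, -0.44 and -0.37, and those of Dlg4 gave -1.44 and 0.13. By limma, 6 of 18625 tested probe sets passed an adjusted p of 0.05: 4 rose and 2 fell. The other 3 calls carry no single gene name: a probe set listed with several genes rose by 0.59 ± 0.07 (adjusted p = 0.0293), while a pair listed with none fell (-1.35 ± 0.14, adjusted p = 0.0155, and -0.96 ± 0.12, adjusted p = 0.0293). In each of these 6 probe sets, all values of one group lay outside those of the other, which chance gives for 10% of probe sets with 3 against 3. At unadjusted p under 0.05 there were 2114 probe sets (1245 with a positive and 869 with a negative log2 change), where 931 would arise by chance. With 1 array left out this unadjusted count ran from 1184 (without control 3) to 2782 (without ketone_6h 1), with 1387 without ketone_1h 3. The values as deposited gave 5 that rose and 4 that fell. Leaving out 1 array gave 0 calls without control 1, control 2, control 3, ketone_1h 1 or ketone_1h 3, 3 without ketone_1h 2, 10 without ketone_6h 1, 6 without ketone_6h 2 and 2 without ketone_6h 3.

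Of 73 subunits of oxidative phosphorylation, which make ATP in mitochondria, 68 had a positive log2 change (median 0.17, mean 0.18). Ndufa2 (0.47 ± 0.09), Atp5mg (0.28 ± 0.07), Atp5mk (0.24 ± 0.06) and Ndufb8 (0.64 ± 0.16) were among 9 that rose adjusted over the list alone, and 0 of the list's members rose over all probe sets. The list holds only probe sets of a single gene. The probe set called at 1 h with several genes (0.59 ± 0.07, adjusted p = 0.0293 by limma) is listed as Atp5mc1l1 and Atp5mc1, so it lies outside the list though its symbols match the list's name pattern. Limma's camera called the list higher (adjusted p = 5.06e-10, and adjusted p = 0.234 with an estimated correlation). The list of ribosomal proteins was also higher, with 47 of 52 log2 changes positive (median 0.15; Rpl14 0.45 ± 0.13, Rpl41 0.27 ± 0.07; adjusted p = 2.04e-06, and adjusted p = 0.234 with an estimated correlation). Its name pattern also took in S6 kinases, and a list without them is given further below. Proteasome subunits, with 33 of 36 positive (median 0.14; Psmd10 0.37 ± 0.12, Psmd7 0.23 ± 0.08), gave adjusted p = 0.0135 (adjusted p = 0.456 with an estimated correlation), and 0.0502 without ketone_1h 2. Targets of the fatty acid sensor PPAR alpha and fatty acid oxidation genes form 1 list, called PPAR alpha targets below. It had a median of 0.17 (Cpt2 0.47 ± 0.14, Pdk4 0.46 ± 0.14). Camera gave adjusted p = 0.0262 (adjusted p = 0.234 with an estimated correlation), with 0.0506 without control 2 and 0.0909 without ketone_1h 2. In these last 3 lists 0 members passed over the list alone or over all probe sets.

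Markers of excitatory neurons were lower at 1 h: all 9 log2 changes were negative, with a median of -0.20 and a mean of -0.38 (Camk2a -0.44 ± 0.14, the cortical transcription factor Tbr1 -1.35 ± 0.47). Their adjusted p was 1.03e-04, and adjusted p = 0.106 with an estimated correlation. Tbr1 had log2 values of 5.96, 4.55 and 5.14 on the 1 h arrays, some under the filter's level of 5.21, so the size of its change rests on low signals. Glutamate receptors and transporters were lower too (26 genes, median -0.11; the kainate receptor Grik2 -0.90 ± 0.27, the metabotropic receptor Grm7 -0.44 ± 0.16; adjusted p = 0.00175, and adjusted p = 0.106 with an estimated correlation). Synaptic vesicle and postsynaptic genes had a median of -0.063 over 26 genes (adjusted p = 0.0153, and adjusted p = 0.234 with an estimated correlation). In that list Camk2b fell by 0.31 ± 0.06 adjusted over the list alone, and 0 members over all probe sets. The call was lost without control 2 (0.0625) and with the values as deposited (0.713). Excitatory neuron and glutamate lists had 0 members passing over the list alone or over all probe sets. RNA quality moved beside these groups: the 3'/5' log2 ratio of the beta-actin control probe sets was 1.35 ± 0.08 (SD, n = 3) in control, 1.85 ± 0.41 at 1 h and 1.84 ± 0.78 at 6 h, where a higher ratio stands for more degraded RNA or shorter labelled copies. The exact 2-sided permutation p was 0.2 at 1 h and 0.4 at 6 h (adjusted 0.6 each over 3 comparisons), and 3 against 3 cannot go below 0.1.

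**Figure D1:**
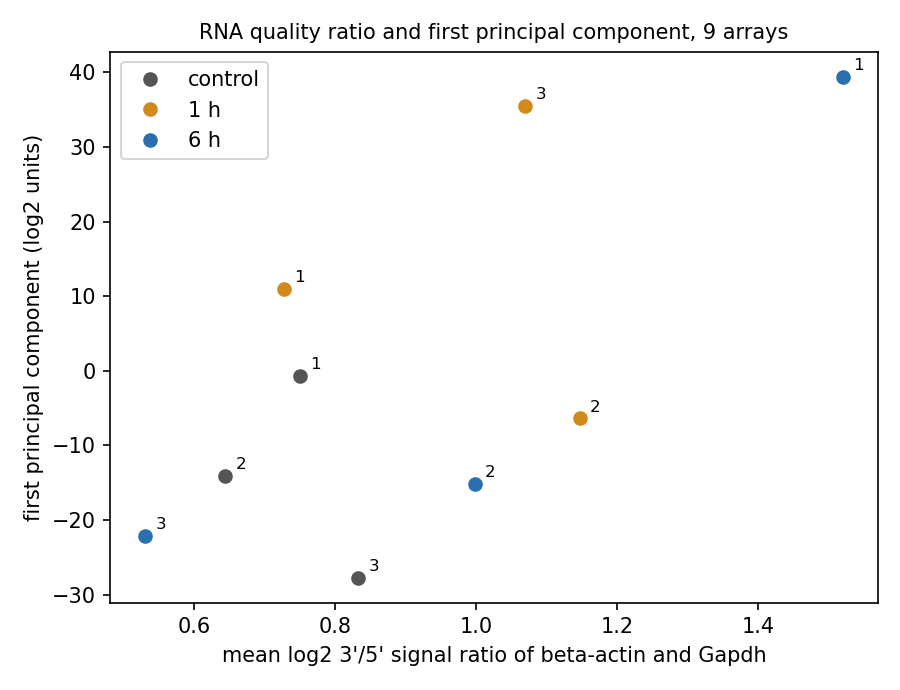
The mean 3'/5' log2 ratio of beta-actin and Gapdh (horizontal axis) and the first principal component of log2 values (vertical axis) for the 9 arrays; numbers are replicate numbers. Array ketone_6h 1 has the highest ratio, 1.52, and the highest component value, 39.4.

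Inflammatory genes were higher at 1 h, with a median of 0.15 and a mean of 0.25 over 23 genes (adjusted p = 0.0161, and adjusted p = 0.314 with an estimated correlation). Adjusted over the list alone, 9 rose and 2 fell, beside 2 (Ccl2 and Cxcl10) that rose over all probe sets. Markers of microglia and macrophages had a median of 0.25 over 14 genes, above that of the inflammatory list. Their mean, 0.14, lay below the mean of the inflammatory list. Their adjusted p was 0.335 by camera and 0.0242 by fry. Icam1, an adhesion molecule for leukocytes, had 0.64 ± 0.15. The immediate early list was not called at 1 h (median 0.068, adjusted p = 0.286), though 9 members rose and 1 fell adjusted over the list alone, among them Gadd45g (0.61 ± 0.10), Klf4 (0.72 ± 0.15) and Maff (0.77 ± 0.18), and 1, Csrnp1, rose over all probe sets. Maff had a control mean of log2 4.90, under the filter's level of 5.21, so the size of its change depends on the pseudocount (1.32 with 1 and 0.34 with 64). Camera called 8 of 36 lists at 1 h, 5 higher and 3 lower, against 0 with an estimated correlation and 15 by fry, a limma test of whether a list moves one way without comparing it with other genes. The median log2 change of all 10707 genes was 0.066.

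The next comparison asked which transcripts differed after 6 h. Ccl2 rose by 1.77 ± 0.13 (adjusted p = 0.00142), a fold of 3.42. Csrnp1 rose by 0.98 ± 0.10 (adjusted p = 0.0265) and Cxcl10 by 0.94 ± 0.12 (adjusted p = 0.0431). The interferon-inducible chemokine Cxcl11 (0.97 ± 0.13, adjusted p = 0.0614) and the secreted protease Adamts1 (0.88 ± 0.12, adjusted p = 0.0814) did not pass. Of genes with negative log2 changes none passed: the cytokine Tnf had -0.83 ± 0.13 (adjusted p = 0.126), Vwa3a -0.95 ± 0.16 (adjusted p = 0.168), Tbl2 -1.01 ± 0.20 (adjusted p = 0.262, with 0.075 ± 0.157 in its other probe set), the synaptic endocytosis gene Pacsin1 -0.79 ± 0.17 (adjusted p = 0.397) and the axonal scaffold Ank3 -0.88 ± 0.19 (adjusted p = 0.402). The 6 h means of Vwa3a, Tbl2 and Pacsin1 lay under the filter's level of log2 5.21, so those sizes depend on the pseudocount: Vwa3a had -1.50 with 1 and -0.45 with 64, Pacsin1 -1.20 and -0.39, and Tbl2 -0.43 with 64 and was not tested with 1. By limma 5 probe sets passed: 4 rose and 1 fell. Of those without a single gene name, a probe set listed with several genes rose (0.66 ± 0.08, adjusted p = 0.0431). It is listed as Mt1f, Ttr and Mt1, so it lies outside the lists that name Ttr or Mt1. Another listed with none, also called at 1 h, fell (-1.15 ± 0.14, adjusted p = 0.0431). All 5 had no overlap between the groups' values, which chance gives for 10% with 3 against 3. At unadjusted p under 0.05 there were 792 probe sets (519 with a positive and 273 with a negative log2 change), fewer than the 931 expected by chance. With 1 array left out this unadjusted count ran from 521 (without ketone_6h 2) to 1605 (without ketone_6h 3), so its side of 931 depends on single arrays. Values as deposited gave 2 that rose and 0 that fell. Leaving out any 1 of the 9 arrays (control 1, 2 or 3, ketone_1h 1, 2 or 3, ketone_6h 1, 2 or 3) left 1 call, and Ccl2 passed at 6 h in all 22 alternative settings.

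**Figure D2:**
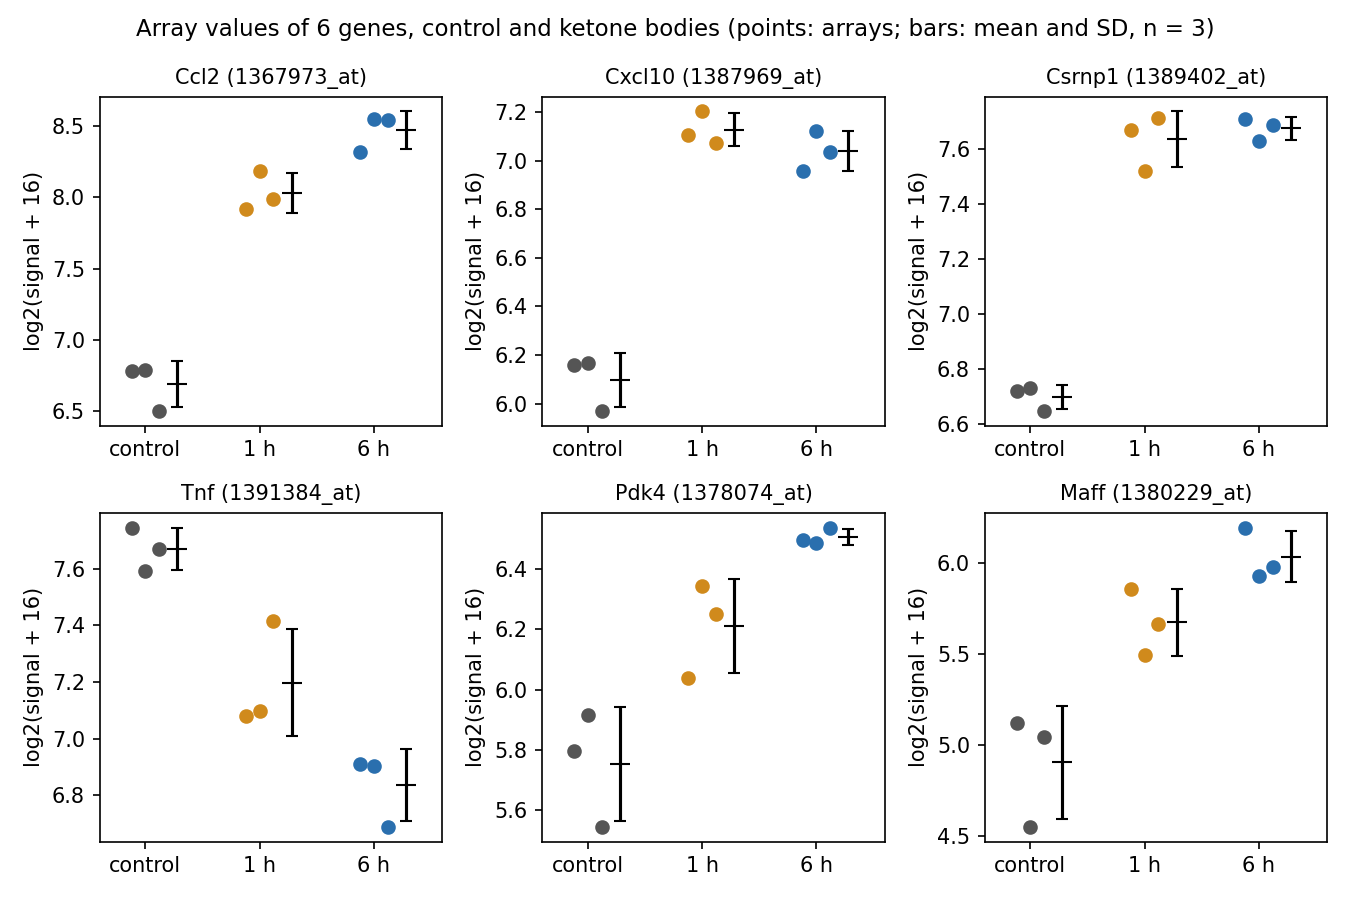
Values of Ccl2, Cxcl10, Csrnp1, Tnf, Pdk4 and Maff on each of the 9 arrays, on a log2 axis of signal plus 16 after quantile normalization; the vertical bars give the mean and SD of 3 arrays. For Ccl2 all arrays at 1 h and 6 h lie above all controls, with log2 changes of 1.34 and 1.77; for Tnf the log2 change at 6 h is -0.83 and did not pass over all probe sets.

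At 6 h inflammatory genes were higher as a group, with a median of 0.30 and a mean of 0.37 over 23 genes (camera adjusted p = 7.08e-09, and adjusted p = 0.0548 with an estimated correlation). Adjusted over the list alone, 11 rose and 1 fell, beside 2 that rose over all probe sets. Cxcl1 (0.87 ± 0.15) was among those that rose over the list alone, and Tnf was the 1 that fell. Immediate early and activity-regulated genes, which respond quickly to signalling and neuronal activity, were higher (41 genes, median 0.18, mean 0.22; adjusted p = 1.75e-06, and adjusted p = 0.0266 with an estimated correlation). In that list 12 rose and 1 fell adjusted over the list alone, including Maff (1.13 ± 0.18), Tiparp (0.66 ± 0.13) and Gadd45g (0.59 ± 0.10), and 1, Csrnp1, rose over all probe sets. For Maff, with its low control signal, the size was 1.82 with a pseudocount of 1 and 0.54 with 64. The phosphatase Dusp1, which damps such signalling, had -0.36 ± 0.09. Markers of excitatory neurons were lower, again with all 9 log2 changes negative (median -0.14, mean -0.32; Neurod6 -0.34 ± 0.12, Tbr1 -1.29 ± 0.47; adjusted p = 1.29e-05, and adjusted p = 0.0411 with an estimated correlation), and 0 members passed over the list alone or over all probe sets. Tbr1 had log2 values of 4.53, 4.89 and 6.38 on the 6 h arrays. The first pair lay under the filter's level of 5.21 and the last within the control range of 6.37 to 6.89.

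Smaller shifts at 6 h were found in 4 more lists, beside a median log2 change of 0.037 over all 10707 genes. Oxidative phosphorylation subunits had 64 of 73 positive log2 changes (median 0.082; Ndufa2 0.27 ± 0.09, Ndufb1 0.35 ± 0.12; adjusted p = 3.64e-04, and adjusted p = 0.402 with an estimated correlation), with 0.0689 without control 3 and 0.41 without ketone_6h 2. The ribosomal list, S6 kinases included, had 44 of 52 positive (median 0.088; Rplp0 0.22 ± 0.07, Rps15a 0.26 ± 0.10; adjusted p = 6.51e-04, and adjusted p = 0.305 with an estimated correlation), with 0.118 without ketone_6h 2. Potassium channels were lower (28 genes, median -0.064; the delayed rectifier Kcna2 -0.56 ± 0.17, the A-type channel Kcnd2 -0.49 ± 0.17; adjusted p = 0.00586, and adjusted p = 0.0891 with an estimated correlation), with 0.118 without ketone_6h 2. These 3 lists had 0 members passing over the list alone or over all probe sets. PPAR alpha targets were higher (16 genes, median 0.11; adjusted p = 0.0092, and adjusted p = 0.111 with an estimated correlation): Pdk4, which restrains pyruvate oxidation (0.76 ± 0.14), and Angptl4 (0.49 ± 0.12) rose adjusted over the list alone and 0 over all probe sets. That call was lost without ketone_6h 2 (0.102) or ketone_6h 3 (0.0781). Camera called 7 lists at 6 h, 5 higher and 2 lower, against 2 with an estimated correlation (immediate early genes and excitatory neuron markers) and 7 by fry. With an estimated correlation only the immediate early list remained once the 3'/5' ratio was a covariate (adjusted p = 0.03), and 0 lists without the 2 arrays farthest out on the first principal component, both settings chosen after seeing the data. The count ran from 3 to 11 when 1 array was left out.

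**Figure D3:**
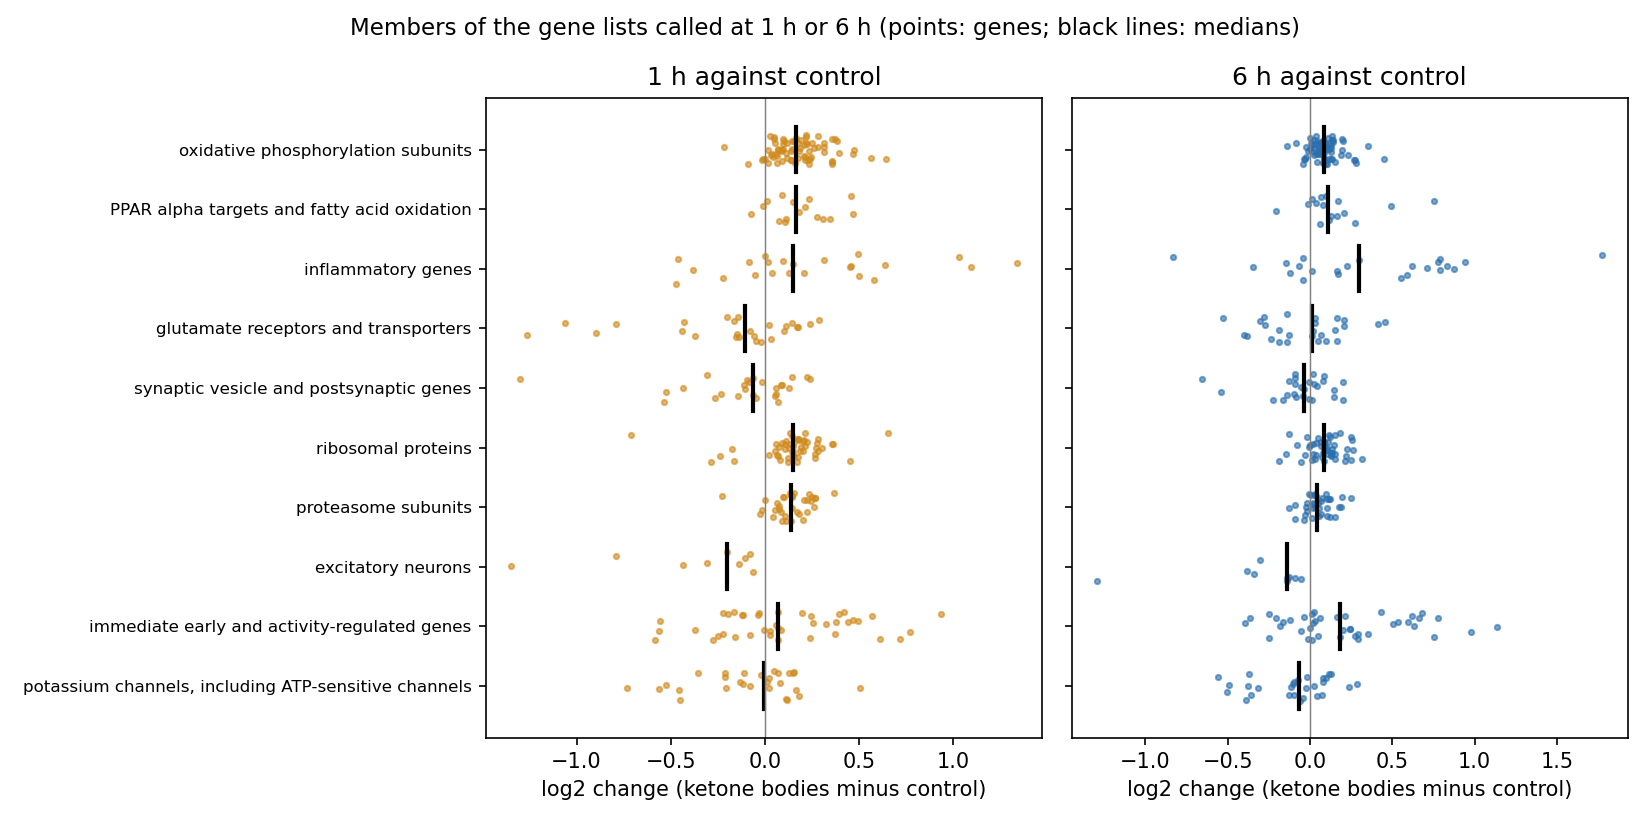
Log2 changes against control (horizontal axes, ketone bodies minus control) of each gene in the lists that camera called at 1 h or 6 h, with the scales of the panels set separately; points are genes and black lines are medians. The 73 oxidative phosphorylation subunits form a narrow band with medians of 0.17 at 1 h and 0.082 at 6 h, while the 23 inflammatory genes spread widely, with medians of 0.15 and 0.30.

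The remaining comparison set 6 h against 1 h, the direct test of a difference between the exposure times. By limma 0 probe sets passed (lowest adjusted p = 0.689), beside 507 at unadjusted p under 0.05 and 931 expected by chance. Every alternative fit by limma, array weights included, also gave 0 that passed. The unadjusted count was 1296 with array weights, and with 1 array left out it ran from 380 (without ketone_1h 3) to 1572 (without ketone_6h 1). The smallest p values with positive log2 changes belonged to Lrrc14 (0.54 ± 0.11), Fam13b (0.52 ± 0.11, and 0.057 ± 0.154 in its other probe set), Snhg11 (0.55 ± 0.12), Meg3 (0.50 ± 0.12) and Ccnl1 (0.46 ± 0.12), and those with negative ones to Fam171a2 (-0.86 ± 0.18), the retinoid receptor Rxrg (-0.50 ± 0.12), the chemokine Ccl19 (-0.66 ± 0.16), Dact2 (-0.43 ± 0.11) and Tbl2 (-0.80 ± 0.20, and 0.11 ± 0.16 in its other probe set), each with an adjusted p of 0.996. Ccl2 had 0.44 ± 0.13 and the cytokine Il1b 0.65 ± 0.20, with the same adjusted p of 0.996. A group mean under log2 5.21 makes the size depend on the pseudocount for Fam171a2 (-1.61 with 1, -0.36 with 64), Ccl19 (-0.99 and -0.32), Il1b (1.07 and 0.30) and Tbl2 (-0.33 with 64, not tested with 1).

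As groups, immediate early genes were higher at 6 h than at 1 h (median 0.12, mean 0.11; Fosb 0.45 ± 0.17, Maff 0.36 ± 0.18; camera adjusted p = 3.08e-04, and adjusted p = 0.081 with an estimated correlation). Inflammatory genes (median 0.13; adjusted p = 0.00495, and adjusted p = 0.489 with an estimated correlation) were higher too, but not without ketone_1h 1 (0.0988), ketone_6h 2 (0.175) or ketone_6h 3 (0.11). Glutamate receptors and transporters were also higher (median 0.074; Glul 0.18 ± 0.07 and -0.076 ± 0.387 in another probe set, Grik2 0.66 ± 0.27; adjusted p = 0.00495, and adjusted p = 0.162 with an estimated correlation), with 0.11 without ketone_6h 3. Choroid plexus and ependyma markers were higher (7 genes, all positive, median 0.12; adjusted p = 0.0107, and adjusted p = 0.489 with an estimated correlation): the thyroid hormone carrier Ttr rose by 0.19 ± 0.06 adjusted over the list alone and 0 over all probe sets, after it fell by 0.21 ± 0.06 at 1 h against control over the list alone, with means of log2 12.17 in control, 11.96 at 1 h and 12.15 at 6 h. The list gave 0.0616 without ketone_1h 1 and 0.376 without ketone_6h 2. Oxidative phosphorylation subunits were lower, with 62 of 73 negative (median -0.10; Atp5mg -0.19 ± 0.07, Cox7c -0.20 ± 0.07; adjusted p = 9.44e-07, and adjusted p = 0.536 with an estimated correlation), and gave 0.0648 without ketone_6h 1. The ribosomal list, S6 kinases included, with 44 of 52 negative (median -0.086; Rpl26l1 -0.40 ± 0.19, Rpl39 0.60 ± 0.26; adjusted p = 0.00342, and adjusted p = 0.536 with an estimated correlation), gave 0.245 without ketone_1h 2 and 0.358 without ketone_6h 1. Proteasome subunits (median -0.071; Psma2 -0.29 ± 0.11, Psmb3 -0.20 ± 0.09; adjusted p = 0.0107, and adjusted p = 0.613 with an estimated correlation) gave 0.0917 without ketone_1h 1, 0.11 without ketone_1h 2 and 0.814 without ketone_6h 1. Apart from Ttr, 0 members of these 7 lists passed over the list alone, and 0 over all probe sets. With an estimated correlation 0 lists were called, and by fry 1. The count by camera was 4 to 7 with 1 array left out. Over all 10707 genes the median log2 change, 6 h minus 1 h, was -0.026.

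Across the 3 groups, limma's moderated F test called 4 probe sets (lowest adjusted p = 0.00381), beside 1185 at unadjusted p under 0.05. This count ran from 1 to 5 with 1 array left out. The changes at both times against control shared 4 called probe sets, 3 that rose (Ccl2, Cxcl10 and Csrnp1) and 1 without a gene name that fell. Simulated unchanged groups that shared the 3 controls gave 0.01 on average (0 to 1), and independent lists would share 0.000859 higher and 0.000107 lower. The simulated probe sets were drawn independently of each other, and the independent lists leave out the shared controls. Neither holds the variation that probe sets share across arrays, so neither bounds what chance gives here. Across probe sets, which are not independent replicates, the log2 changes at 1 h and 6 h correlated at 0.743 against 0.502 in the simulations (0.471 to 0.526), with a covariance of 0.0399 against 0.0184, a difference of 0.0215. The controls are too few to split, so part of the excess may come from the shared controls. The overlap was 0 without control 1, control 2 or control 3. That loss is not particular to the controls. Calls at 1 h were also 0 without ketone_1h 1 or ketone_1h 3, and 6 h kept 1 call whichever array was left out.

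Genes of ketone body use showed no change that passed. The ketone body dehydrogenase Bdh1 had 0.053 ± 0.156 at 1 h and -0.14 ± 0.16 at 6 h (0.025 ± 0.166 and 0.043 ± 0.166 in its other probe set), and Oxct1, which activates acetoacetate for oxidation, had -0.072 ± 0.078 and -0.021 ± 0.078. The transporter Slc16a1 had 0.042 ± 0.10 and 0.14 ± 0.10, and Slc16a7, a neuronal ketone body and lactate transporter, -0.67 ± 0.28 (adjusted p = 0.416) and -0.32 ± 0.28 (adjusted p = 0.987). Both Oxct1 values turned positive with the values as deposited (0.0032 and 0.02) and with arrays centred on their medians (0.064 and 0.064). Pdk4 had 0.46 ± 0.14 (adjusted p = 0.352) and 0.76 ± 0.14 (adjusted p = 0.236) over all probe sets. The activity marker Fos had -0.16 ± 0.12 and 0.014 ± 0.123, the first turning positive (0.011) with arrays centred on their medians, and the growth factor Bdnf -0.16 ± 0.25 and -0.035 ± 0.251. The other Bdnf probe set had the opposite sign, with 0.49 ± 0.25 at 1 h and 0.014 ± 0.247 at 6 h. The ketone list as a whole was not called (8 genes; median 0.042, adjusted p = 0.547 at 1 h; median -0.053, adjusted p = 0.721 at 6 h).

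Beside the immediate early list at 1 h, other lists that were not called had single members that passed adjusted over the list alone, and 0 over all probe sets. In the unfolded protein and integrated stress response list, Ppp1r15a, a stress-induced phosphatase subunit, rose by 0.80 ± 0.15 at 1 h and 0.95 ± 0.15 at 6 h, and the transcription factor Atf4 by 0.39 ± 0.08 and 0.34 ± 0.08. The list's adjusted p was 0.988 and 0.808. Interneuron markers parted at 1 h: Pvalb (0.65 ± 0.13), Sst (0.37 ± 0.07) and Vip (0.32 ± 0.10) rose over the list alone, and Reln fell by 0.40 ± 0.11 (list adjusted p = 0.323). The metal-binding Mt2A rose over the list alone in the FOXO and glucocorticoid lists (0.73 ± 0.10 at 1 h, 0.63 ± 0.10 at 6 h), and so did the clock genes Nr1d1 (0.58 ± 0.13) and Nfil3 (0.64 ± 0.16) at 6 h. The microglial gene Aif1 (0.75 ± 0.17) and the chaperone Cryab (0.40 ± 0.10) rose over their lists at 1 h. The granule cell marker Prox1 fell by 0.39 ± 0.11 at 1 h over its list, while Kcnj4 rose by 0.50 ± 0.11.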

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

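The tests of cell numbers (fewer neurons, more microglia), by median and by mean, the fits with the 3'/5' covariate and the choice of the 3 patterns came after results were seen; the counts of other sample splits were planned.

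Differences between the exposure times in 7 gene lists drew attention because the direct test of 6 h against 1 h called them. Their mean log2 differences, 6 h minus 1 h, were -0.09 for oxidative phosphorylation, -0.0506 for ribosomal proteins, -0.0834 for proteasome subunits, 0.113 for immediate early genes, 0.116 for inflammatory genes, 0.154 for glutamate receptors and transporters, and 0.149 for choroid plexus markers. With an estimated correlation 0 of them remained called. For 3 genes every array at 1 h moved one way from the control mean and every array at 6 h the other: Fam13b (0.524, 6 h minus 1 h), Rxrg (-0.495) and Ccl19 (-0.658). For Fam13b this holds for 1 probe set only, since the other had -0.16 at 1 h and -0.099 at 6 h. That difference was not tested by this rule itself, and limma gave an adjusted p of 0.996 for each. Outside the tested probe sets, the control probe set for 5S ribosomal RNA was 0.353 higher at 1 h than in control on the log2 scale, and the one for the 3' end of Gapdh 0.164 higher, each with every array above every control (exact permutation p = 0.1, the smallest possible for 3 against 3).

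The first pattern is the higher oxidative phosphorylation and ribosomal protein lists at 1 h, beside the higher 3'/5' ratio in arrays ketone_1h 2 and ketone_1h 3. With that ratio as a covariate, 97.2% of the members' mean log2 change remained (83.4% to 111% with 1 array left out). This argues against RNA integrity as the whole cause only as far as the ratio follows it within groups. The ratio averages beta-actin, which differed at 1 h (0.50), with Gapdh, which did not (-0.025). With group terms in the fit its slope rests on differences within groups alone. Degradation that it follows poorly would stay in the change, so the test cannot exclude RNA integrity. Part of the ribosomal list were S6 kinases taken in by name; without them 45 genes had a mean of 0.18 (adjusted p = 6.15e-09 with the preset correlation, and adjusted p = 0.234 with an estimated correlation). A response to ketone bodies, which feed mitochondrial oxidation, may remain, untested here. The control's unknown exposure time and preparation stay open too.

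The next pattern is the lower excitatory neuron and glutamate receptor lists at 1 h, which share 2 genes and so do not stand as separate evidence. With the ratio as covariate 85.4% of their mean log2 change remained (75.8% to 90.6%), which argues against RNA integrity as the whole cause only with the same limit. The hexokinase control probe sets, left out of the ratio, had log2 changes of -0.70 (5' end), -0.64 (middle) and -0.21 (3' end) at 1 h. RNA integrity is therefore not excluded for this pattern. Fewer neurons of all kinds would lower interneuron markers alike, and their median (0.15, 11 genes) lay 0.289 above that of the members (-0.14, 33 genes; 95% bootstrap interval over genes 0.0525 to 0.467), which met the bound written for excluding it, but the mean, compared later, lay 0.257 above (-0.0976 to 0.548) with an interval that holds 0. Those markers went both ways, with 8 positive and 3 negative (fry adjusted p = 0.00693 towards higher values, camera adjusted p = 0.323). Over the list alone 3 rose, among them Sst (0.37 ± 0.07), and 1 fell, Reln (-0.40 ± 0.11), while Gad2 (-1.30 ± 0.51) did not pass. The GABA list, which shares Gad1, Gad2 and Slc32a1 with the interneuron markers, had a mean of -0.16 (adjusted p = 0.0585), so fewer neurons and lower expression within them cannot be told apart. Fewer excitatory neurons alone, or lower expression in them after ketone bodies, could give the pattern and was not tested.

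The last pattern is the higher inflammatory and immediate early lists at 6 h. With the ratio as covariate 102% of the mean log2 change remained (99.6% to 104%), which argues against RNA integrity as the whole cause only as far as the ratio follows it within groups. For more microglia, the median of the 11 inflammatory members that rose over the list lay 0.638 above that of the 14 microglial markers (95% interval 0.47 to 0.807), which met the bound written for excluding it, but that bound was wrong because it used members picked for having risen; the comparisons of all members were added after gene values were seen, the mean last. Over all 63 members the median lay 0.0635 above that of the markers (-0.132 to 0.266) and the mean 0.186 above (0.038 to 0.342). Over the 23 inflammatory members alone the median lay 0.149 above (-0.173 to 0.631) and the mean 0.278 above (0.0328 to 0.533). Over the 41 immediate early members alone the median lay 0.0333 above (-0.175 to 0.232) and the mean 0.125 above (-0.0269 to 0.283). The markers ran from -0.38 (Cx3cr1) to 0.40 (Aif1), with 0.028 ± 0.071 for Ctss. These intervals, and those for the interneuron markers, resample genes with their log2 changes held fixed. They leave out the spread between arrays and treat genes as independent, so an interval above 0 does not settle the question. The answer also turns on the summary and the list taken, and more microglia and a response within cells cannot be told apart. A response to ketone bodies, and one to time in fluid or to preparation, may each lie behind it, since the control's exposure time is not given.

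The covariate ended most single calls while the log2 changes moved by less than their errors. At 1 h Cxcl10 went from 1.03 ± 0.12 to 1.05 ± 0.12 (adjusted p = 0.0563) and Csrnp1 from 0.94 ± 0.10 to 0.94 ± 0.11 (adjusted p = 0.0563). At 6 h Cxcl10 went from 0.94 ± 0.12 to 0.96 ± 0.13 (adjusted p = 0.145) and Csrnp1 from 0.98 ± 0.10 to 0.98 ± 0.12 (adjusted p = 0.0925). The probe sets listed with no gene came slightly nearer 0: from -1.35 ± 0.14 to -1.33 ± 0.15 (adjusted p = 0.0563) and from -0.96 ± 0.12 to -0.93 ± 0.12 (adjusted p = 0.0867) at 1 h, and from -1.15 ± 0.14 to -1.11 ± 0.15 (adjusted p = 0.145) at 6 h. Those listed with several genes went from 0.59 ± 0.07 to 0.59 ± 0.08 (adjusted p = 0.0867) at 1 h and from 0.66 ± 0.08 to 0.66 ± 0.09 (adjusted p = 0.151) at 6 h. The errors grew and the residual degrees of freedom fell from 6 to 5, so the calls ended mainly through wider errors and fewer degrees of freedom. Ccl2 kept its call at both times (1.37 ± 0.14, adjusted p = 0.0495, and 1.81 ± 0.14, adjusted p = 0.00503).

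Other splits of the same arrays were counted. Splits of 3 against 3 number 10, too few for a share under 0.05. At 1 h, 1 of the 10 splits, the real one, gave as many as 6 probe sets (highest other 0), and 1 gave as many as 8 lists (highest other 3). At 6 h, 1 gave as many as 5 probe sets (highest other 0) and 1 as many as 7 lists (highest other 6). For 6 h against 1 h, 10 of the 10 splits gave at least the real 0 probe sets, with 857 in the split of ketone_1h 1, ketone_1h 3 and ketone_6h 1 from the rest, and 1 gave as many as 7 lists (highest other 4). Across the 3 groups, 9 of 100 splits drawn from 280 gave at least the real 4 probe sets, so chance cannot be excluded; the highest, 843, put the same 3 arrays together. Counts this far above the real ones point to a structure of the samples that crosses the groups.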

How the results depend on the processing

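The 3'/5' covariate, the fits without the 2 arrays farthest out on the first principal component and the narrower ribosomal list, with either correlation, were chosen after seeing the data; the others were planned. None of those chosen beforehand was left out.

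Against the main counts of 6 (1 h), 5 (6 h), 0 (6 h against 1 h) and 4 (across the 3 groups), 0 probe sets were called for 6 h against 1 h in every alternative. Values as deposited called 9 at 1 h and 2 at 6 h (6 and 2 shared with the main calls), and arrays centred on their medians called 10 and 2 (6 and 2 shared). Without the filter on dim probe sets there were 3 and 2 calls, where more probe sets are adjusted for. Array weights called 25 at 1 h, 6 at 6 h and 24 across the groups. Only the 2 groups compared gave 5 and 1, and 1 probe set per gene, with fewer tests, gave 10, 11 and 7 across the groups. The 3'/5' covariate gave 1, 1 and 1, and leaving out the 2 farthest arrays, ketone_6h 1 and ketone_1h 3, gave 0, 1 and 1, with fewer arrays in the fit. A pseudocount of 1 gave 7 and 6, one of 64 gave 7 and 5, the 60th percentile 6 and 5, and no intensity trend 8 and 5. Elsewhere the cause was not tested. With 1 array left out the counts ran from 0 to 10 at 1 h, from 1 to 1 at 6 h, from 0 to 0 for 6 h against 1 h and from 1 to 5 across the groups.

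The overlap of 4 probe sets became 2 with values as deposited and 2 with arrays centred on their medians, and ran from 0 to 0 with 1 control left out. The replicate numbers do not show a pairing: 3 of 9 pairs of arrays correlated above 0.1 (-0.36 to 0.539), and 4 of 9 arrays correlated best with their own number. With the replicate block the calls were 2 at 1 h, 1 at 6 h, 0 for 6 h against 1 h and 1 across the groups, and the overlap was 1.

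Gene lists called by camera numbered 8, 7 and 7. An inter-gene correlation estimated from the data gave 0, 2 and 0, and fry gave 15, 7 and 1. The estimate exceeded the preset 0.01 for the oxidative phosphorylation (0.182), proteasome (0.168), choroid plexus (0.122), ribosomal (0.0882), inflammatory (0.0709) and synaptic (0.0376) lists. It was under 0.01 for excitatory neurons (-0.0616), immediate early genes (-0.0144), glutamate receptors (-0.0105), PPAR alpha targets and potassium channels. There a higher correlation cannot explain the larger p, and other causes were not tested. Values as deposited called 11 lists at 6 h, and so did the fit without the 2 farthest arrays (11). With the 3'/5' covariate and an estimated correlation the counts were 0, 1 (immediate early genes, adjusted p = 0.03) and 0, and without the 2 farthest arrays and an estimated correlation 0, 0 and 0 (immediate early genes at 6 h, adjusted p = 0.0869). With 1 array left out they ran from 6 to 10 at 1 h, 3 to 11 at 6 h and 4 to 7 for 6 h against 1 h. The narrower ribosomal list of 45 genes kept its calls with the preset correlation, with means of 0.18 (adjusted p = 6.15e-09), 0.10 (adjusted p = 4.6e-05) and -0.075 (adjusted p = 2.05e-04), and lost all 3 with an estimated correlation (adjusted p = 0.234, 0.305 and 0.536). With that list and an estimated correlation 0, 2 and 0 lists were called. The beta-actin ratio differed from control by 0.50 at 1 h and 0.49 at 6 h, and by 0.45 and 0.48 after quantile normalization. Before normalization the 6 h arrays had 2.58, 1.92 and 1.03 against 1.37, 1.27 and 1.42 in control. The 6 h difference thus leans on ketone_6h 1, and ketone_6h 3 lay below every control. Over the alternatives in which lists were tested, including those that leave out an array, the lists called kept the direction given by the test. Of these values 341 stayed past the threshold and 121 did not. Without the filter, PPAR alpha targets at 6 h (0.0666) and, for 6 h against 1 h, glutamate receptors (0.0549) and choroid plexus markers (0.0712) lost their calls, and without the 2 farthest arrays so did proteasome subunits for 6 h against 1 h (0.548).

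Of 273 pairs of a named gene or called probe set and a comparison, 11 were called, 6 of them with a single gene name, and 0 of these turned sign. Ccl2 at 6 h passed in 22 of 22 settings (adjusted p 0.00015 to 0.021) and at 1 h in 16 (0.00166 to 0.131). Csrnp1 passed in 11 at 1 h (0.00317 to 0.183) and 9 at 6 h (0.00569 to 0.224), and Cxcl10 in 10 at 1 h (0.00317 to 0.162) and 6 at 6 h (0.0152 to 0.283). A further 14 pairs passed in some setting: at 1 h Got1 in 7, Cxcl1 in 6, Camk2a in 4, Meg3 and Mt2A in 2 each, and Dlg4, Gadd45g, Setd1b and Snhg11 in 1 each; at 6 h Cxcl11 in 4 and Adamts1, Maff, Ppp1r15a and Tnf in 1 each. Another 23 turned sign in some setting, for causes not tested.

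At 1 h against control, these turned sign: Oxct1 with values as deposited (0.0032) and arrays centred on their medians (0.064), Mobp likewise (0.029 and 0.089), Olig1 with those (0.071 and 0.13) and with array weights (0.027), Fos with centring (0.011), and Slc16a1 without the 2 farthest arrays (-0.012). With 1 array left out, Olig1 ran from -0.067 to 0.055, Slc16a1 from -0.018 to 0.073, Bdh1 from -0.0079 to 0.16 and Bdnf from -0.34 to 0.027.

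At 6 h against control, Oxct1 turned with values as deposited (0.0196), centring (0.064), array weights (0.016) and without the 2 farthest arrays (0.022). Bdnf turned with array weights (0.18), the 3'/5' covariate (0.051) and without the 2 farthest arrays (0.24), Olig1 with the same 3 (-0.0073, -0.0018 and -0.023), Bdh1 with the covariate (0.015) and Pdgfra with centring (0.019). With 1 array left out, Fos ran from -0.069 to 0.10, Olig1 from -0.041 to 0.062, Oxct1 from -0.048 to 0.022, Bdnf from -0.23 to 0.24 and Pdgfra from -0.089 to 0.037.

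For 6 h against 1 h, Olig1 turned with values as deposited (-0.00044), centring (-0.017) and array weights (-0.035), Oxct1 with centring (-0.00035), and Man1a1 (-0.065), Amigo2 (-0.055), Olig2 (-0.089) and Hbb (0.024) with array weights. Abcb1a turned without the 2 farthest arrays (-0.088). With 1 array left out, Bdnf ran from -0.064 to 0.41, Man1a1 from -0.046 to 0.15, Amigo2 from -0.041 to 0.14, Olig2 from -0.22 to 0.56, Olig1 from -0.032 to 0.063, Hbb from -0.15 to 0.030, Alas2 from -0.073 to 0.19, Abcb1a from -0.020 to 0.30 and Bok from -0.093 to 0.023. The filter's level of log2 5.21 is the 40th percentile and no background was measured, so how far low signal limits these genes is unknown.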

Other observations

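The relation of RNA quality to the main axis of variation was tested after the arrays had been seen; the values of the marker lists come from planned tests.

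The mean 3'/5' log2 ratio of beta-actin and Gapdh went with the first principal component over the 9 arrays: Pearson's r was 0.667 (permutation p = 0.0491) and Spearman's rho 0.5 (permutation p = 0.178). Without the 2 arrays farthest from the median ratio, ketone_6h 1 and ketone_1h 2, r was 0.509, and within groups it was 0.627. The beta-actin ratio was highest in ketone_6h 1 at 2.58. The Gapdh ratio was 0.132 ± 0.111 (SD, n = 3) in control, 0.107 ± 0.039 at 1 h and 0.19 ± 0.23 at 6 h (exact permutation p = 0.8 each). The 5' control probe set of hexokinase lay below every control in every array at 1 h (-0.704 on the log2 scale; exact permutation p = 0.1).

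Among the lists that were not called, 28 at 1 h, 29 at 6 h and 29 for 6 h against 1 h, the lowest adjusted p by camera was 0.0559, for potassium channels at 1 h. The test, the median and the mean differed in sign for 11 lists at 1 h, 7 at 6 h and 5 for 6 h against 1 h, none of them called. At 6 h glutamate receptors and transporters had a median of 0.014, a mean of -0.044 and a test towards lower values (adjusted p = 0.216). At 1 h oligodendrocyte markers had a median of 0.010, a mean of -0.036 and a test towards lower values (adjusted p = 0.17). Median log2 changes of other marker lists at 1 h were 0.25 for microglia and macrophages (14 genes, adjusted p = 0.335; more microglia was weighed for 6 h only), 0.016 for astrocytes (11 genes, adjusted p = 0.373) and 0.047 for endothelial cells (11 genes, adjusted p = 0.988). The microglial list shares 0 genes with the other lists. Ctss had a mean signal of 2000 in control and 2140 at 6 h (log2 change 0.028 ± 0.071), Fcer1g had 436 and 505, and P2ry12 392 and 324.

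Among lists of energy and stress genes at 1 h, the median was 0.043 for glycolysis (adjusted p = 0.909), 0.051 for the citric acid cycle (adjusted p = 0.323), 0.16 for NRF2 antioxidant genes (adjusted p = 0.825), 0.078 for heat shock genes (adjusted p = 0.323), 0.082 for hypoxia-inducible genes (adjusted p = 0.547) and 0.14 for apoptosis genes (adjusted p = 0.0636). At 6 h the FOXO list had 0.11 (adjusted p = 0.101). The erythroid gene Hbb, described only because its list has 2 genes measured, had 0.39 ± 0.12 at 1 h and 0.32 ± 0.12 at 6 h, with no overlap with the control values, which chance gives for 10% with 3 against 3. Alas2, the other, had 0.18 ± 0.16 and 0.25 ± 0.16. None of these passed (adjusted p from 0.335 to 0.987), and blood in the samples was not tested as a source of the inflammatory changes at either time.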
